A study of Homo sapiens with 12 samples.

How the data were processed

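Transcript levels were measured in RCC4 and UMRC2, a pair of established human kidney cancer lines that lack a functional VHL tumour suppressor. Each line had been made to carry stably an empty vector (EV) or a fusion of FoxO1 or FoxO3 to the ligand-binding part of the estrogen receptor (ERT2). In both fusions the 3 AKT phosphorylation sites were replaced by alanine, and 4-hydroxytamoxifen (4OHT) brings the fusion into the nucleus. Each of the 6 engineered lines was treated for 12 h with 100 nM 4OHT or with ethanol as vehicle, and total RNA was labelled with biotin and hybridised to Affymetrix U133 Plus 2.0 arrays. Each of the 12 combinations has 1 array, so the number of arrays limits the precision.

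The deposited values are intensity per probe set on a linear scale. Per the labels the authors made them with MAS5, without a stated version or scaling target. The deposited arrays shared no common level: their median intensity ran from 71.1 to 138.7. Before the data were examined, the gene lists, the comparisons, the rule for named genes and the settings had been fixed, with the values to be used as deposited. The arrays were then quantile-normalised instead, a switch made after the array levels were seen and before any comparison was fitted; the counts with the values as deposited stand among the alternatives. Values under the 20th percentile, an intensity of 18.0 or log2 4.17, were raised to it and all values were put on the log2 scale.

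Of 54675 probe sets, 62 were controls and 41097 had 1 gene symbol in the annotation. The 1801 with several symbols and the 11777 with none were kept out of the gene table. For each of 19775 genes the probe set with the highest mean was used, and 14285 genes that reached the array median in at least 2 arrays were tested. Genome positions were not used here.

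The response of each engineered line was the log2 level with 4OHT minus that with vehicle. The 6 responses were fitted in limma 3.58.1 (R 4.3.3) with construct and cell line as terms, which leaves 2 residual degrees of freedom, and with a prior variance that follows the mean level (prior degrees of freedom 5.46). The n of each construct is 2 cell lines. With the line term fitted, a p-value measures how far construct effects differ between the lines, array noise included. It says nothing of repeat cultures of 1 line. The FoxO1 and FoxO3 responses were compared with the EV response, together and singly, and with one another. A fit with a term for the difference between the lines in the FoxO response, a fit of the 6 vehicle arrays for fusion against EV, and a fit of the same arrays for RCC4 against UMRC2 completed the set. In the first of these the FoxO1 and FoxO3 pairs of a cell line stood as its replicates. In the last its EV, FoxO1 and FoxO3 lines did. All tests are two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Errors after ± are standard errors from limma.

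The 27 gene lists, among them FoxO targets taken from general knowledge of the field, were tested against all other genes with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Counts of members were taken over all genes tested and also adjusted over the list alone. The form with an estimated correlation also took its p-value from only 2 residual degrees of freedom, which leaves it little power. No list kept its call with an estimated correlation in any comparison of the responses, of the vehicle fusion lines or of the cell lines. These losses therefore do not show that correlation between genes alone removed the calls.

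The genes named are the 10 higher and 10 lower genes with the largest change past the threshold whose sign was the same in every single-line value, or 5 each as plain values where fewer than 5 genes passed. To these were added 5 higher and 5 lower genes per single-line dataset with no value at the floor in the 4 arrays behind that dataset, up to 4 members of each list by size of change, and a fixed set of FoxO genes, ESR1 and known FoxO targets. XIST, TSIX and Y-linked genes were left out of the naming. Among 218 named genes, 22 had another bright probe set with the opposite sign.

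On simulated responses with the same spread, the test of FoxO against EV recovered 73% of genes changed by log2 2 and 19% of those changed by log2 1. The test of FoxO1 alone recovered 45% at log2 2, and that of the difference between the lines 3%. Alternatives covered the scaling, the floor, the filter, the choice of probe set, the prior variance, the terms of the model, the list test, the fold threshold and leaving out each vehicle and 4OHT pair. The arrays were checked by their spike-in probe sets and by the ratio of 3-prime to 5-prime signal, which ran from 0.917 to 1.05 for GAPDH and from 1.09 to 1.27 for ACTB.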

Results

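The series asked which transcripts FoxO1 and FoxO3, transcription factors that AKT keeps out of the nucleus, control in kidney cancer cells. The 12 h time point was chosen to favour early events. The data are 12 arrays, 1 for each combination of cell line (RCC4 or UMRC2), construct (EV, FoxO1 or FoxO3) and treatment (vehicle or 4OHT). They form 6 pairs of vehicle and 4OHT arrays, with 2 pairs for each construct. No group has a replicate array, so the cell lines serve as the replicates where constructs are compared.

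The fusion transcripts were visible through the estrogen receptor part of the constructs. Of 9 ESR1 probe sets, 5 were at least log2 2 above EV in all 4 fusion lines without 4OHT. Their median level was 9.17 in RCC4 FoxO1, 12.42 in RCC4 FoxO3, 12.22 in UMRC2 FoxO1 and 13.15 in UMRC2 FoxO3, against 5.24 and 4.59 in the RCC4 and UMRC2 EV lines. Taken probe set by probe set, the median ratio of the FoxO3 line to the FoxO1 line was 9.03 in RCC4 and 2.07 in UMRC2. The spike-in probe sets put the arrays at separate scan levels as deposited. In 5 RCC4 arrays their geometric mean lay between 4903 and 5468, while the RCC4 FoxO3 array with 4OHT stood at 2859 and the 6 UMRC2 arrays lay between 2642 and 2874.

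**Figure D1:**
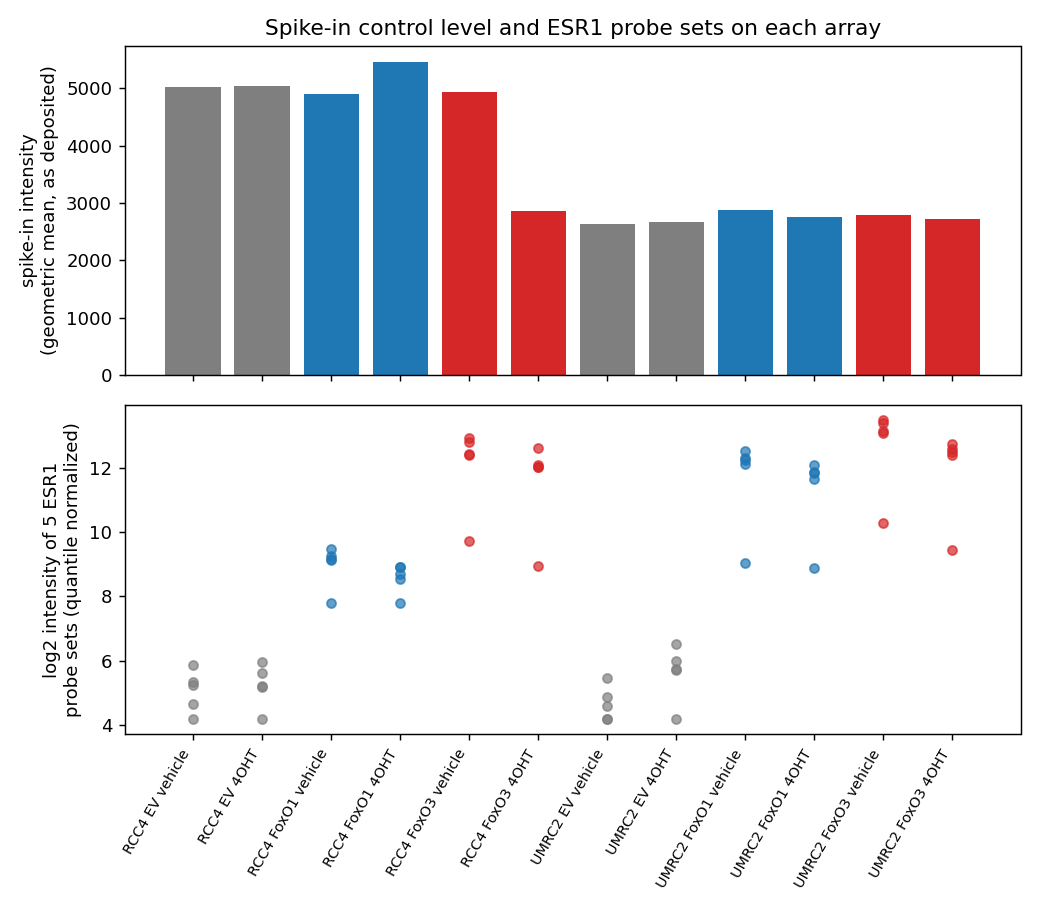
Top, bars give the geometric mean intensity of the spike-in probe sets on each of the 12 arrays as deposited; bottom, points give the log2 level of 5 ESR1 probe sets on each array, coloured by construct. The RCC4 FoxO3 array with 4OHT stands at 2859 beside 4903 to 5468 in the other RCC4 arrays, and the ESR1 points are lowest in the EV lines.

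The first comparison asked what activation of either FoxO changed beyond 4OHT itself. Since the ESR1 probe sets were low in the EV lines, an effect of 4OHT through the ERT2 part was not separated from that of FoxO. Among the 10 largest increases were CLTRN, a kidney membrane protein that supports amino acid transport (log2 5.35 ± 0.33, adjusted p = 0.00209), TPPP, which promotes tubulin polymerisation (5.19 ± 0.48, adjusted p = 0.00439), and SLC40A1, the cellular iron exporter (4.68 ± 0.43, adjusted p = 0.00439). IGFBP1, a secreted binder of insulin-like growth factors, rose by 5.30 ± 1.23 (adjusted p = 0.0434), with single-line values from 1.30 to 8.38 and 2 arrays at the floor. DEPP1, a FoxO-regulated protein (4.98 ± 0.76), and CCN2, a matricellular growth factor (3.95 ± 0.61), rose too. The nucleotide receptor gene P2RY2 (-3.75, adjusted p = 0.0384) and the nuclease gene AEN, a p53 target (-2.55 ± 0.31, adjusted p = 0.00678), were among the largest decreases. ARHGAP33 fell by 3.16 ± 0.38 on the log2 scale, but its other bright probe set gave 0.52. Each of these genes had the same sign in all 4 FoxO lines.

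The G1/S and G2/M lists were lower on average over the isoforms. Of 38 measured G1/S and DNA replication genes, 21 were lower and 0 higher (31 and 0 adjusted over the list alone), with a median of -0.83 and adjusted p = 5.32e-18 by camera, or adjusted p = 0.306 with an estimated correlation. Among them were the helicase genes MCM2 (-1.45, adjusted p = 0.00598) and MCM3 (-1.43, adjusted p = 0.00439) and the DNA repair gene UNG (-1.44). Of 40 G2/M and mitosis genes, 18 were lower and 0 higher (32 and 0 adjusted over the list alone), with a median of -0.60 and adjusted p = 2.69e-15, or adjusted p = 0.297 with an estimated correlation. CDC20, an activator of the anaphase ubiquitin ligase, changed by -1.25 and cyclin A2, CCNA2, by -1.15. Both isoforms enter these values, but under FoxO1 alone the G2/M list had a median of 0.01 (adjusted p = 0.954). CDC20 ranged from -2.64 to 0.10 over the lines. Of 18 cell cycle inhibitors, 4 were higher and 0 lower (6 and 2 adjusted over the list alone), with a median of 0.38 and adjusted p = 0.00493, or adjusted p = 0.32 with an estimated correlation. They included BTG1, an antiproliferative factor (2.03, adjusted p = 0.00397), CDKN1B, the p27 inhibitor of cyclin-dependent kinases (1.10 ± 0.14, adjusted p = 0.0069), and CCNG2 (1.33 ± 0.18, adjusted p = 0.00893).

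Lists of ribosome, lipid and hypoxia genes were lower as well, on average over the isoforms. Under FoxO1 alone the cholesterol and hypoxia lists did not pass. Relative to EV, cholesterol medians in RCC4 and UMRC2 were -0.03 and -0.29 for FoxO1 and -0.49 and -1.09 for FoxO3. Hypoxia medians in the same lines were -0.02 and -0.07 for FoxO1 and -0.17 and -0.40 for FoxO3. Of 37 ribosome biogenesis genes, 23 were lower and 0 higher (33 and 0 adjusted over the list alone), with a median of -0.996 and adjusted p = 1.35e-18, or adjusted p = 0.297 with an estimated correlation. POLR1B, a subunit of RNA polymerase I (-2.05), and the assembly factors TSR1 (-1.92) and NLE1 (-1.98) were the largest, and MYC, which drives many such genes, changed by -2.20 (adjusted p = 0.00995). Of 14 fatty acid synthesis genes, 7 were lower and 0 higher (9 and 0 adjusted over the list alone), with a median of -0.87 and adjusted p = 7.76e-06, or adjusted p = 0.297 with an estimated correlation. ACACA, which makes malonyl-CoA (-1.77), and FASN, the fatty acid synthase (-1.22), were among them. Of 19 cholesterol synthesis genes, 7 were lower and 0 higher (9 and 0 adjusted over the list alone), with a median of -0.43 and adjusted p = 2.57e-05, or adjusted p = 0.441 with an estimated correlation. SQLE, squalene epoxidase (-1.17), was one; IDI1 (-1.13) had 2 of its 4 bright probe sets with the opposite sign. Of 38 hypoxia-inducible factor targets, 7 were lower and 2 higher (11 and 4 adjusted over the list alone), with a median of -0.16 and adjusted p = 0.0328, or adjusted p = 0.326 with an estimated correlation. The lower ones included the glycolytic kinase gene HK2 (-1.81), VEGFA, which codes for an angiogenic factor (-1.70), and DDIT4, an inhibitor of mTORC1 (-1.69).

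Known FoxO targets went both ways. Of 48 measured, 11 were higher and 4 lower (20 and 4 adjusted over the list alone), with a median of 0.65 and adjusted p = 2.57e-05, or adjusted p = 0.32 with an estimated correlation. Both isoforms enter these values, but under FoxO1 alone the list did not pass. Its medians relative to EV in RCC4 and UMRC2 were 0.13 and 0.006 for FoxO1, against 0.96 and 0.66 for FoxO3. TNFSF10, the death ligand TRAIL (2.89, adjusted p = 0.015), the transcription regulators CITED2 (1.94 ± 0.25, adjusted p = 0.00766) and KLF6 (1.90 ± 0.27, adjusted p = 0.0101) and the repressor BCL6 (1.35 ± 0.32, adjusted p = 0.0485) rose. Cyclin D1, CCND1, which the labels give as a known target, fell by 2.28 ± 0.21 on the log2 scale (adjusted p = 0.00439), and TXNIP, a brake on glucose uptake, fell by 1.07 ± 0.17 (adjusted p = 0.0127). Values that did not pass were 2.16 ± 1.02 for SESN3 (adjusted p = 0.261), 1.94 ± 0.72 for PDK4 (adjusted p = 0.156), 1.36 ± 0.51 for SESN1 (adjusted p = 0.16), -0.02 for BNIP3 (adjusted p = 0.928) and -0.04 for TRIB1 (adjusted p = 0.951). Of 38 autophagy and lysosome genes, 6 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.24 and adjusted p = 1.68e-05, or adjusted p = 0.297 with an estimated correlation. GABARAPL1, a component of autophagosomes (1.63), and the autophagy receptor gene OPTN (0.86) were among the higher.

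By limma, 441 genes were higher and 675 lower under FoxO than under EV, 1116 in all, with 3306 at an unadjusted p under 0.05. The count was 617 without the RCC4 EV pair, 278 without the UMRC2 EV pair and 528 without the UMRC2 FoxO1 pair; it was 184 with the values as deposited and 367 with the mean of a gene's probe sets. It was 0 without the filter on dim probe sets (3405 at an unadjusted p under 0.05), with a constant prior variance (2732) or with the isoforms as replicates (1663), so the calls rest on these choices; in that last fit, setting the FoxO3 pairs apart in place of the EV pairs gave 1428 genes.

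**Figure D2:**
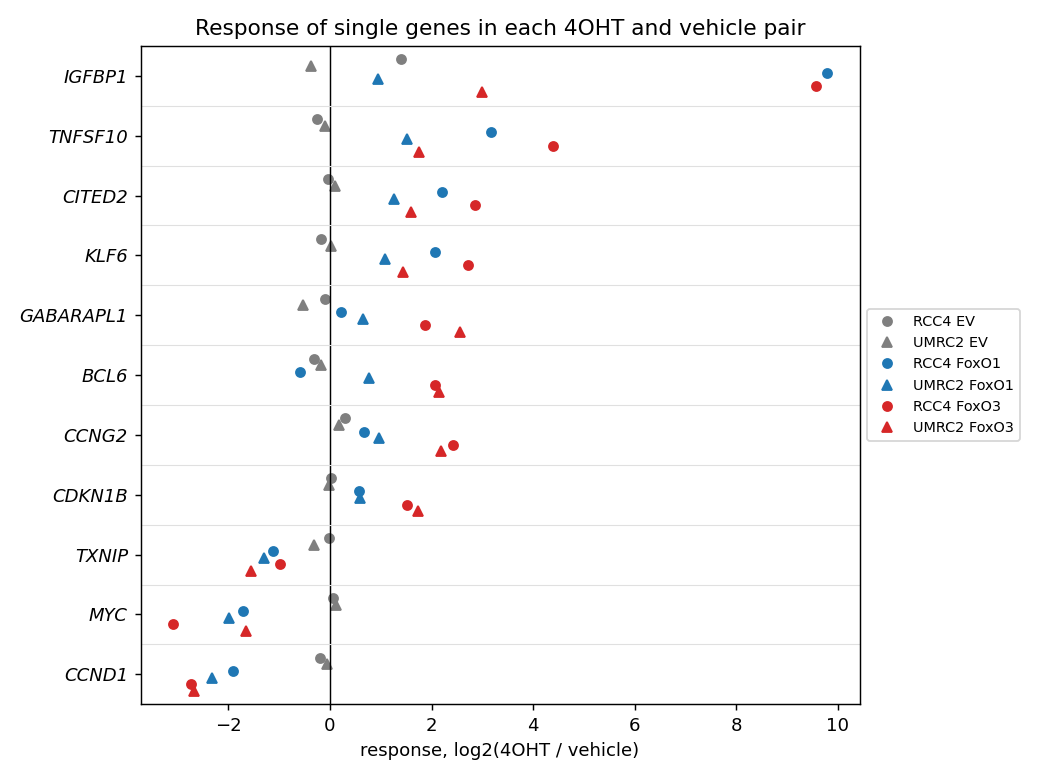
Points give the log2 response to 4OHT (4OHT minus vehicle) of 11 genes in each of the 6 pairs, with colour for the construct and marker shape for the cell line. CCND1 and MYC lie below 0 and KLF6 and CITED2 above 0 in the FoxO lines, while IGFBP1 spans the widest range between the cell lines.

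The response to FoxO1 alone was narrow at this threshold. CLTRN rose most (4.97 ± 0.38, adjusted p = 0.0301), and the histamine-degrading enzyme gene HNMT (2.80), CYP27A1, a sterol hydroxylase (2.69), and the tight junction gene CLDN1 (2.44 ± 0.21) rose as well. NEDD4L, a ubiquitin ligase that controls renal sodium channels (2.21), and SNAP23, a membrane fusion protein (1.64 ± 0.16), were also higher, each in both lines. CCND1 gave -1.98 (adjusted p = 0.0518).

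As lists, ribosome biogenesis (0 members higher and 17 lower adjusted over the list alone, median -0.61, adjusted p = 2.55e-17), G1/S genes (0 and 5, -0.41, adjusted p = 3.99e-12) and fatty acid synthesis (0 and 6, -0.54, adjusted p = 0.000113) were lower under FoxO1. Cell cycle inhibitors (1 and 0 adjusted over the list alone, median 0.24, adjusted p = 0.0227) and autophagy genes (0 and 0, 0.11, adjusted p = 0.034) were higher. All 5 lists had adjusted p = 0.468 with an estimated correlation, and none of their members passed over all genes. By limma 12 genes were higher and 0 lower, with 1431 at an unadjusted p under 0.05. The count was 0 without the UMRC2 FoxO1 pair, 189 without either FoxO3 pair (108 higher and 81 lower), 71 without the RCC4 EV pair (53 and 18) and 37 without the UMRC2 EV pair (34 and 3). It was 0 without the filter, with a constant prior variance or with the mean of a gene's probe sets.

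FoxO3 alone gave larger values for most of the same gene groups. TPPP (7.33 ± 0.55, adjusted p = 0.00103), SLC40A1 (5.86 ± 0.49, adjusted p = 0.00146), CLTRN (5.74 ± 0.38, adjusted p = 0.00103) and DEPP1 (5.85) rose, as did IGFBP1 (5.76 ± 1.42, adjusted p = 0.0315), and RBP4, the plasma retinol carrier, gave 5.28 with 8 arrays at the floor. CDCA7, a MYC-responsive cell division gene (-3.54 ± 0.24, adjusted p = 0.00103), EFNA3, an ephrin ligand gene (-3.68), and AEN (-3.51) were among the largest decreases. PDK4, a kinase that restrains pyruvate oxidation (3.96, adjusted p = 0.0179), the MYC antagonist gene MXI1 (1.34, adjusted p = 0.00715) and SESN1, a stress-induced mTORC1 inhibitor (2.11, adjusted p = 0.0487), rose, and CCND1 (-2.57, adjusted p = 0.00146) fell.

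Under FoxO3 the G2/M list stood at a median of -1.15, with 35 of 40 members lower and 0 higher over all genes and also 35 and 0 adjusted over the list alone (adjusted p = 8.83e-21, or adjusted p = 0.268 with an estimated correlation). G1/S genes had 29 of 38 lower (32 adjusted over the list alone), a median of -1.29 and adjusted p = 4.99e-17, and ribosome biogenesis 27 of 37 (34 adjusted over the list alone), a median of -1.34 and adjusted p = 5.37e-17. With an estimated correlation these became adjusted p = 0.285 and adjusted p = 0.268. Fatty acid synthesis (9 lower and 1 higher of 14, median -1.07, adjusted p = 1.78e-05, adjusted p = 0.268 with an estimated correlation) and cholesterol synthesis (9 lower of 19, median -0.81, adjusted p = 4.01e-06, adjusted p = 0.373 with an estimated correlation) fell, with 11 and 13 lower adjusted over the list alone. FoxO targets had 20 higher and 5 lower of 48 (26 and 6 adjusted over the list alone), a median of 1.02 and adjusted p = 2.66e-06, and autophagy genes 13 higher and 1 lower of 38 (16 and 1 adjusted over the list alone), a median of 0.38 and adjusted p = 4.01e-06. With an estimated correlation these became adjusted p = 0.285 and adjusted p = 0.268.

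Smaller shifts under FoxO3 were a median of -0.39 for hypoxia-inducible factor targets (11 lower and 4 higher of 38, 18 and 4 adjusted over the list alone, adjusted p = 0.0128), 0.37 for cell cycle inhibitors (6 higher and 1 lower of 18, 7 and 3 adjusted over the list alone, adjusted p = 0.00976) and 0.25 for mTORC1 and PI3K signalling (11 higher and 5 lower of 42, 13 and 5 adjusted over the list alone, adjusted p = 0.0272). With an estimated correlation the first of these lists and the inhibitors had adjusted p = 0.285, and the signalling list adjusted p = 0.373. VEGFA fell by 2.85 on the log2 scale, and PIK3IP1, a member of the signalling list that restrains PI3K, gave 4.55. By limma 942 genes were higher and 1430 lower, with 4317 at an unadjusted p under 0.05. The count was 1276 without the UMRC2 EV pair, 583 with the values as deposited (126 higher and 457 lower), 1440 with the mean of a gene's probe sets, and 0 without the filter or with a constant prior variance.

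**Figure D3:**
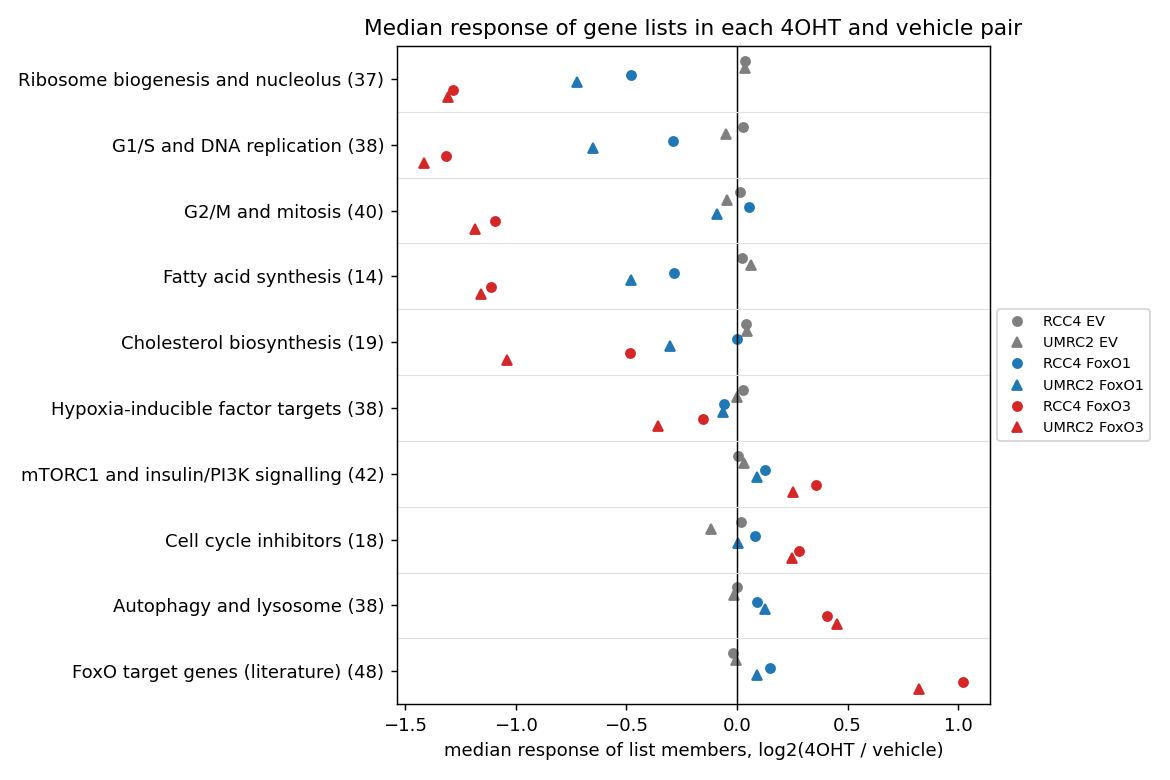
Points give the median log2 response to 4OHT (4OHT minus vehicle) of 10 gene lists in each of the 6 pairs, with colour for the construct and marker shape for the cell line. G2/M genes sit at -1.09 and -1.18 under FoxO3 in RCC4 and UMRC2 and at 0.05 and -0.09 under FoxO1, while ribosome biogenesis genes lie below 0 under both.

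The isoforms were then compared directly, and mitosis genes parted them most. Of 40 G2/M genes, 33 were lower under FoxO3 than under FoxO1 and 0 higher (36 and 0 adjusted over the list alone), with a median of -1.10 and adjusted p = 1.07e-30, or adjusted p = 0.337 with an estimated correlation. CDC20 differed by -2.27 ± 0.16 (adjusted p = 0.00543), the mitotic kinesin gene KIF20A by -2.10, CCNA2 by -1.92 and CCNB1, cyclin B1, by -1.63 (adjusted p = 0.00737). SATB1, a chromatin organiser (5.56 ± 1.18, adjusted p = 0.039), PDK4 (4.03 ± 0.83, adjusted p = 0.0363), PIK3IP1 (3.83 ± 0.42, adjusted p = 0.00881) and TPPP (4.27 ± 0.55, adjusted p = 0.0123) were higher under FoxO3, and EFNA3 (-3.90 ± 0.60, adjusted p = 0.0198) and the Polycomb gene CBX2 (-2.66) were lower. CCND1 differed by -0.59 (adjusted p = 0.209).

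Also lower under FoxO3 than FoxO1 were G1/S genes (15 of 38, 25 adjusted over the list alone, median -0.82, adjusted p = 4.13e-13), ribosome biogenesis (10 of 37, 18 adjusted over the list alone, -0.71, adjusted p = 2.05e-10), cholesterol synthesis (6 of 19, 9 adjusted over the list alone, -0.54, adjusted p = 7.64e-07) and fatty acid synthesis (4 of 14, 8 adjusted over the list alone, -0.53, adjusted p = 0.00117). Hypoxia-inducible factor targets (7 lower and 2 higher, 9 and 2 adjusted over the list alone, median -0.18, adjusted p = 0.0296) followed. FoxO targets (11 higher and 2 lower, 16 and 3 adjusted over the list alone, median 0.70, adjusted p = 2.6e-06), autophagy (6 and 0, 10 and 0 adjusted over the list alone, 0.26, adjusted p = 1.88e-05), the mTORC1 and PI3K list (4 and 2, 7 and 4 adjusted over the list alone, 0.17, adjusted p = 0.0239) and cell cycle inhibitors (4 and 0, 5 and 3 adjusted over the list alone, 0.25, adjusted p = 0.0372) were higher. All 9 lists had adjusted p = 0.337 with an estimated correlation. The mTORC1 and PI3K list holds members that restrain the pathway, such as PIK3IP1, so its direction is not that of the pathway's activity. By limma 309 genes were higher and 521 lower, 830 in all, with 3106 at an unadjusted p under 0.05; among those lower, the median response was -0.18 under FoxO1 and -1.32 under FoxO3. The count was 32 without the RCC4 FoxO1 pair and 194 without the UMRC2 FoxO1 pair, 46 with the values as deposited, 147 with the mean of a gene's probe sets, and 0 without the filter or with a constant prior variance. The fusion transcript was more abundant in the FoxO3 lines, and the RCC4 FoxO3 pair spans both scan levels.

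The response to 4OHT without a FoxO fusion was read from the EV lines. In EV cells limma called 0 genes, with 340 at an unadjusted p under 0.05, and 3 without the RCC4 EV pair. The test recovered 42% of simulated changes of log2 1. Without a test, 731 genes in RCC4 EV and 784 in UMRC2 EV changed at least 2-fold against their own vehicle. The largest values with the same sign in both lines were 2.44 for GLRA2, a glycine receptor gene, 2.23 for SLC26A6, an anion exchanger gene, and -2.30 for BDKRB1, a kinin receptor gene, each at adjusted p = 1. The 5 measured endothelial markers were lower as a list (0 members past the test, also adjusted over the list alone, median -0.46, adjusted p = 0.0283, adjusted p = 0.928 with an estimated correlation). This list was dim: its array medians ran from 4.87 to 5.66, between the floor of 4.17 and the median of all probe sets at 6.62. Because GLRA2 and GPR173 had high values here (2.44 and 2.11), their values relative to EV, -2.75 and -2.47, lie mostly on the EV side.

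Whether the FoxO response differed between the cell lines was tested as an interaction. The FoxO1 and FoxO3 pairs of a line stood as its replicates, beside its single EV pair. A difference between the isoforms therefore adds to the error of this test, and the simulated changes held none. NF-kB and cytokine genes differed as a list, with a median of -0.68 for RCC4 minus UMRC2 over 18 genes (0 members past the test, also adjusted over the list alone, adjusted p = 0.00246, adjusted p = 0.947 with an estimated correlation). The neutrophil chemokine genes CXCL8 (-2.36 ± 1.12) and CXCL1 (-1.27 ± 0.87) and the monocyte chemokine gene CCL2 (-2.15) had adjusted p = 1. By limma 0 genes differed, with 337 at an unadjusted p under 0.05, in a test that recovered 3% of simulated changes of log2 2.

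Leakiness of the fusions without 4OHT was looked for in the 6 vehicle arrays. ESR1, which reads the fusion, was 6.96 ± 0.54 above EV (adjusted p = 0.12); GLRA2, measured against the same EV vehicle arrays as its EV response, gave 2.50 and GABRB1, a GABA receptor gene, 2.06. By limma 0 genes passed, with 1029 at an unadjusted p under 0.05, and up to 4 when 1 line was left out, the 4 without UMRC2 FoxO1. The limma test did not call even ESR1, although it recovered 78% of simulated changes of log2 2. A lack of calls therefore does not exclude leakiness. List medians were 0.08 for G1/S genes (adjusted p = 0.00284), -0.10 for G2/M genes (adjusted p = 1.67e-07), -0.06 for oxidative phosphorylation (adjusted p = 0.000161) and 0.10 for immediate early genes (adjusted p = 0.0499). With an estimated correlation the first 3 had adjusted p = 0.705 and the last adjusted p = 0.738, and 0 members passed, also adjusted over the list alone.

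The cell lines themselves differed widely without 4OHT. RCC4 had more AMBP, a plasma protease inhibitor precursor (8.63 ± 0.13), UCHL1, a deubiquitinase (8.09), the aldo-keto reductase gene AKR1B10 (7.74, adjusted p = 2.19e-07) and PHGDH, the entry enzyme of serine synthesis (6.55). UMRC2 had more of the adhesion gene AMIGO2 (-9.37 ± 0.10, adjusted p = 2.19e-07), the matrix genes CTHRC1 (-8.95) and SPOCK1 (-8.16), NNMT, nicotinamide N-methyltransferase (-8.14), and the chemokine gene CXCL5 (-7.48). Of the 12 arrays, AMBP had 6 at the floor, CXCL5 5, SPOCK1 3, CTHRC1 and PHGDH 2 each and AMIGO2 1. The differences of these genes may be understated where a floored array is among the vehicle arrays fitted. As lists, oxidative phosphorylation was higher in RCC4 (28 of 41 higher and 5 lower, also 28 and 5 adjusted over the list alone, median 0.43, adjusted p = 0.000137), as were G2/M genes (22 and 5, the same adjusted over the list alone, median 0.19, adjusted p = 0.0214). Lower in RCC4 were p53 targets (16 of 24, 17 adjusted over the list alone, -0.89, adjusted p = 0.000137), interferon-stimulated genes (16 of 26, 17 adjusted over the list alone, -0.95, adjusted p = 0.00089), immediate early genes (16 of 26, 17 adjusted over the list alone, -0.55, adjusted p = 0.00081) and cholesterol synthesis (16 of 19, 17 adjusted over the list alone, -0.63, adjusted p = 2.05e-05). FoxO targets (23 lower and 9 higher, 23 and 10 adjusted over the list alone, -0.27, adjusted p = 0.00822) and NF-kB genes (9 and 4, 10 and 4 adjusted over the list alone, -0.82, adjusted p = 0.0243) were lower too. All 8 had adjusted p = 0.574 with an estimated correlation. By limma 3804 genes were higher and 3379 lower in RCC4, with 8000 at an unadjusted p under 0.05. With the values as deposited 9182 were higher and 1227 lower. All RCC4 vehicle arrays had the higher scan level and all UMRC2 arrays the lower one, by a ratio of 1.84, so small differences cannot be told apart from the scan level in these arrays. Within the lower level, between the FoxO3 arrays with 4OHT, 6327 of the 7183 genes had the same sign, with AMBP at 8.62 and AMIGO2 at -9.05.

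Taken line by line and normalised to the EV response, without a test, DEPP1 (5.36) was the highest value in RCC4 FoxO1, TPPP (7.56) in RCC4 FoxO3, CLTRN (5.52) in UMRC2 FoxO1 and NTN4, a netrin (6.36), in UMRC2 FoxO3. The lowest were JAKMIP2 (-4.99), MYL10 (-5.71), SPRR2G (-4.87) and TAS1R2 (-4.49) in the same order. These are the extremes among genes with no value at the floor in the 4 arrays behind each value. A change of at least 2-fold was seen in 1722 genes for RCC4 FoxO1, 3701 for RCC4 FoxO3, 2029 for UMRC2 FoxO1 and 3527 for UMRC2 FoxO3, and 1440 genes differed that much between the EV responses of the lines.

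Against each line's own vehicle, 82 genes were at least 2-fold higher in all 4 FoxO lines, where independent lines would give 0.222, and 48 were lower, where they would give 0.306. The EV responses of both lines, without FoxO, shared 51 higher genes against 11.9 for independent lines and 38 lower against 8.28, and the FoxO1 responses shared 139 against 26.3 and 112 against 23.5. Since the EV responses also exceeded independence, the excess in the FoxO lines cannot be read as due to FoxO alone. Across genes, which are not independent replicates, the FoxO3 responses of the lines had a Pearson correlation of 0.550 (Spearman 0.535), the FoxO1 responses 0.246 (0.277) and the EV responses 0.0172 (0.0356). Within UMRC2 the FoxO1 and FoxO3 responses had 0.487 and within RCC4 0.332.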

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

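The tests on the size of the FoxO3 response, on its fusion transcript and on the G2/M genes were chosen only after the result was seen; the level of UMRC2 genes was a test planned before, and the limit it sets on a share of UMRC2 RNA was added after.

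FoxO3 activation gave the larger response, with 830 genes past the test for a difference from FoxO1. Noise from the low scan level of the RCC4 FoxO3 array with 4OHT is argued against as the whole cause: in UMRC2, on 1 scan level, the SD across genes was 1.41 times that of FoxO1 (95% gene bootstrap interval 1.38 to 1.44, which leaves out the variation between arrays), and the covariance with the UMRC2 FoxO1 response was 2.13 times as large for RCC4 FoxO3 as for RCC4 FoxO1 (1.92 to 2.34). UMRC2 RNA in that array is argued against as the whole cause: 14 genes bright in UMRC2 and near the floor in RCC4 had a median there 0.50 above EV and -0.12 from FoxO1 among the RCC4 arrays with 4OHT, which just missed the bound set beforehand, so the argument rests on the limit added after, 4.33% or less of their UMRC2 level, a share too small to give the 1725 genes that were at least 2-fold lower. More fusion transcript in the FoxO3 lines, by a median of log2 3.18 in RCC4 and 1.05 in UMRC2 over 5 probe sets, stays open. Each level comes from 1 line, and the values go both ways. UMRC2 FoxO1 (level 12.22, SD of the response 0.623) lay near RCC4 FoxO3 in level (12.42, SD 0.947). In SD it lay near RCC4 FoxO1 (level 9.17, SD 0.603), which goes against this explanation. An SD counts noise too, and that of RCC4 EV, without a fusion, was 0.459. Going with the explanation, the SD of FoxO3 over that of FoxO1 was larger in RCC4 (1.57) than in UMRC2 (1.41). The covariance of UMRC2 FoxO1 with RCC4 FoxO3 (0.197) was also above that of RCC4 FoxO1 with UMRC2 FoxO3 (0.122). A difference in action between the isoforms, which the design names, also stays open and untested.

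G2/M genes fell under FoxO3 and lay near 0 under FoxO1. If the FoxO1 response were a scaled-down FoxO3 response, the G2/M median under FoxO1 would be -0.30 in RCC4 and -0.51 in UMRC2. The observed medians were 0.05 and -0.09, above these by 0.35 (0.29 to 0.40) and 0.42 (0.31 to 0.57), while G1/S genes differed by 0.06 and -0.04; other lists with an interval off 0 were ribosome biogenesis in RCC4 (-0.14, -0.25 to -0.02) and UMRC2 (-0.16, -0.30 to -0.04), FoxO targets in UMRC2 (-0.26, -0.45 to -0.00169) and cholesterol synthesis in RCC4 (0.13, 0.05 to 0.33). The intervals treat genes as independent and are too narrow, and each median rests on 1 pair of arrays. A threshold in fusion level would have to lie between UMRC2 FoxO1 (level 12.22, G2/M median -0.09) and RCC4 FoxO3 (12.42, -1.09) or differ between the lines, and it was not tested apart from a difference between the isoforms.

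Of 8 groups of array measures tested, the RCC4 FoxO3 array with 4OHT stood apart in both median intensity and spike-in signal; about 1 group in 20 would do so by chance. Its median intensity was 74.6, with 121.2 in the nearest other RCC4 array, and the gap was 0.727 of the range. Its spike-in mean was 2859, with 4903 in the nearest, and the gap was 0.783 of the range.

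NF-kB and cytokine genes differed between the lines in their FoxO response, with a median of -0.68 for RCC4 minus UMRC2, adjusted p = 0.00246, or adjusted p = 0.947 with an estimated correlation, and 0 of 18 members passed (337 of all genes had an unadjusted p under 0.05 by limma). The medians relative to EV were -0.33 and -0.43 for FoxO1 and FoxO3 in RCC4, and 0.25 and 0.12 in UMRC2.

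Outside the gene table, 2 probe sets annotated to both FOXO3 and FOXO3B, the former being the gene in the construct, were above EV without 4OHT in both FoxO3 lines. One was higher by 6.98 in RCC4 and 3.40 in UMRC2 on the log2 scale, and in the FoxO1 lines it gave 1.42 and -0.04; the other was higher by 2.59 and 3.13, with 0 and 1.42 in the FoxO1 lines. They were picked after their values were seen; of 13522 probe sets outside the table, 7 were at least log2 2 above EV in both FoxO3 lines, 3 in both FoxO1 lines, and 3 at least log2 2 below in both FoxO3 lines.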

How the results depend on the processing

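The trimmed-mean scaling and the values as deposited were added after the array levels were seen, the latter having been the setting written first, and the regrouping of the pairs was chosen after the results were seen. With the values as deposited the genes past the threshold were 184 for FoxO, 583 for FoxO3 and 46 for FoxO3 against FoxO1, and 1 each for the difference between the lines and for the fusion without 4OHT; 7193 genes reached 2-fold in RCC4 FoxO3. That setting put the median response of all genes at -0.88 in RCC4 FoxO3 and -0.30 in UMRC2 FoxO1, against -0.08 and -0.01 with quantile scaling, and 166, 545 and 39 of these genes were also called under the quantile scaling. It called 15 genes for FoxO1, of which 3 were shared. Trimmed-mean scaling gave 21 genes for FoxO1 and shared 1068 of the FoxO and 2306 of the FoxO3 calls. Relative to all genes, the list medians for G1/S genes (FoxO against EV) were -0.78 with quantile scaling, -0.81 as deposited and -0.81 with the trimmed mean.

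A floor at the 40th percentile gave 36 genes for FoxO1 (27 higher and 9 lower). Without the filter on dim probe sets limma called 0 genes for FoxO, FoxO1, FoxO3 and FoxO3 against FoxO1 (3405, 1719, 4284 and 3133 at an unadjusted p under 0.05), 3254 and 3546 genes reached 2-fold in RCC4 and UMRC2 FoxO1, and 0 lists were called in EV cells. With the filter at the 75th percentile, which tests fewer genes, the counts were 37 for FoxO1 (27 higher and 10 lower) and 1 for the fusion without 4OHT; 413, 1937, 685 and 1933 genes reached 2-fold in RCC4 FoxO1, RCC4 FoxO3, UMRC2 FoxO1 and UMRC2 FoxO3; and the correlation between lines was 0.482 for FoxO1 and 0.742 for FoxO3. The mean of a gene's probe sets gave 367, 0, 1440 and 147 for the same 4 tests, with a constant prior variance 0 in each (2732, 1135, 3699 and 2491 at an unadjusted p under 0.05), and no cell line term 2 for FoxO1. Taking the isoforms as replicates gave 0 for FoxO (1663 unadjusted; smallest adjusted p = 0.0553). In that fit, of 9 ways to set apart 1 pair per line, FoxO3 in both lines gave 1428 genes and each other way 0. A difference between the isoforms adds to the error of that fit, but how far it accounts for the lost calls was not tested. For the other changes the cause was not tested either, except where fewer genes were tested.

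An estimated correlation, tested with 2 residual degrees of freedom, left 0 lists past the threshold in each of FoxO, FoxO1, FoxO3, FoxO3 against FoxO1 and EV, from 9, 5, 10, 10 and 1. Against the own vehicle alone, 1140 genes in RCC4 FoxO1 and 1246 in UMRC2 FoxO1 reached 2-fold, beside 731 and 784 in the EV lines. At 3-fold relative to EV the counts were 794, 1644, 817 and 1543. The vehicle and 4OHT arrays of each line were paired throughout; each group has 1 array, so no further block by replicate was fitted.

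Leaving out each pair in turn gave 278 to 1655 genes for FoxO, 0 to 189 for FoxO1, 1276 to 2202 for FoxO3, 32 to 1129 for FoxO3 against FoxO1, 0 to 3 for EV and 0 to 4 for the fusion without 4OHT; an arm left with 1 pair is assumed to vary like the others. The lowest were without UMRC2 EV (278 and 1276), UMRC2 FoxO1 (0) and RCC4 FoxO1 (32). Without the RCC4 FoxO3 pair, which also removes the difference in scan level, the counts were 1431, 189, 1821 and 581. Of the named genes' results over the scaling, floor, filter, probe set, prior variance, line term and leave-one-out alternatives, 2572 kept their side of the threshold, 590 were no longer past it, 41 newly passed and 0 reversed. A reversal was counted only where the result passed in the main or the alternative fit. Many of the genes had been named for a constant sign, so few could reverse. Arrays carry noise near the background: 1.55% or fewer of the gene values of any array lay at the floor. The response of a pair that starts or ends there is understated, while a value relative to EV can be moved either way.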

Other observations

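The ESR1 probe sets were picked after their values were seen; the tests in this part, the count of splits included, were planned before.

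Several genes outside the lists that passed still changed under FoxO relative to EV. Of the immediate early and ERK feedback genes, SPRY2, an inhibitor of receptor tyrosine kinase signalling, was at 2.82 (adjusted p = 0.027) and the ERK phosphatase gene DUSP6 at 2.32 (adjusted p = 0.0175), while FOSL1, an AP-1 subunit, was at -2.21 (adjusted p = 0.00496). Their list had 5 members higher and 3 lower of 26 (7 and 6 adjusted over the list alone), with adjusted p = 0.612. In the mTORC1 and PI3K list, PIK3IP1 was at 2.63 (adjusted p = 0.00877, single-line values from -0.14 to 4.73), ERBB3, a receptor tyrosine kinase, at 2.10 (adjusted p = 0.0161), and TRIB3, a stress-induced pseudokinase, was at -1.92 (adjusted p = 0.00696). The interferon-induced genes IFIT2 (2.00, adjusted p = 0.00853) and IFIT3 (1.31, adjusted p = 0.0167) were higher, but 24 of 26 genes of that list did not pass. HERPUD1, of endoplasmic reticulum quality control (1.61, adjusted p = 0.00598), the collagen gene COL1A2 (2.73, adjusted p = 0.0271) and GPX3, a secreted glutathione peroxidase (1.25, adjusted p = 0.0118), rose. PAX8, a renal lineage transcription factor (-0.88, adjusted p = 0.0107), KRT18, an epithelial keratin (-1.11), TNFRSF10B, a TRAIL receptor (-1.12, adjusted p = 0.0299), and the kinase gene PLK2 (-1.78, adjusted p = 0.0138) fell.

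As lists, 18 of 27 did not pass for FoxO against EV, with medians from -0.23 to 0.46. Adjusted p was 0.0624 for mTORC1 and PI3K signalling, 0.113 for estrogen receptor targets, 0.137 for endothelial markers, 0.294 for interferon-stimulated genes, 0.467 for fatty acid oxidation and for renal tubule markers, 0.582 for haematopoietic markers, 0.699 for apoptosis regulators and 0.754 for NF-kB genes. It was 0.612 for oxidative phosphorylation, p53 targets, TGF-beta targets, immediate early genes and mesenchymal markers, and 0.658 for the MYC network, antioxidant defence, the unfolded protein response and housekeeping genes. The median and the direction of the test had different signs for antioxidant defence (-0.06), interferon-stimulated genes (-0.02) and mesenchymal markers (-0.01), which tested higher. Of markers of other cell types, 5 of 14 endothelial and 11 of 16 haematopoietic genes passed the filter, beside 16 of 21 renal tubule genes. The array medians of the haematopoietic list ran from 5.85 to 6.76, around the median of all probe sets at 6.62.

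The native FoxO genes FOXO1 (0.36, adjusted p = 0.734), FOXO3 (-0.16, adjusted p = 0.826) and FOXO4 (0.51, adjusted p = 0.802) did not pass for FoxO against EV. FOXO1 gave 1.04 ± 0.56 (adjusted p = 0.272) under FoxO3 and -0.32 ± 0.56 (adjusted p = 0.901) under FoxO1, and FoxO3 against FoxO1 had adjusted p = 0.216. Another of its probe sets went from 5.01 to 8.57 with 4OHT in RCC4 FoxO3 and from 7.47 to 8.47 in UMRC2 FoxO3. The remaining one, near the floor, went from 4.17 to 5.81 and from 4.89 to 4.55 in the same order. For FOXO3 the mean of -0.16 joins opposite changes in the FoxO3 lines, each from 1 pair. Its brightest probe set went from 10.14 to 10.92 in RCC4 FoxO3 and from 11.52 to 10.66 in UMRC2 FoxO3. In the same order, others went from 8.71 to 9.62 and 10.01 to 9.03, and from 8.44 to 9.35 and 9.68 to 8.97. The last, near the floor, went from 4.77 to 4.42 and from 4.27 to 4.17. The EV lines carry the ERT2 part according to the labels, yet the 5 ESR1 probe sets that rose in the fusion lines had a median of 5.24 and 4.59 there, near the floor of 4.17.

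For RCC4 against UMRC2 without 4OHT, the real split of the 6 vehicle arrays gave 7183 genes and the highest of the other splits 0. The 10 possible splits, of which 1 gave as many genes, are too few for a share under 0.05.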
